A study of Bacteria with 17 samples.

How the data were processed

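The series holds 17 arrays made from surface seawater taken at the Pacifica pier, from which microbes under 1 micron were collected. Seawater was incubated in 1 L bottles at 16 °C for 12 h with isotope-labelled substrates, per the labels' protocols. Chip-SIP measures extracted RNA on an array of rRNA probes, where the brightness of a spot gives the amount of RNA bound and the isotope ratio of the same kind of spot gives the heavy isotope that the RNA carries. 3 arrays hold fluorescence (no isotope at T0, the nucleic acid incubation, and the ammonium and glucose incubation) and 14 hold isotope signals, 1 array for each substrate: 10 substrates carried 13C and 4 carried 15N.

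The fluorescence files hold intensity on a linear scale, of RNA labelled with the dye Alexafluor 532 per the labels' protocols. The scanner, the extraction of spots and any normalization are not given in the sources used here. The deposited intensity values reach a ceiling of 65535, and 46 of the probes used lay at it on at least 1 array. Each fluorescence file has 5083 probes of 107 taxa, with 22 to 51 probes for each taxon, and 156 linker control spots whose values are the same on all 3 arrays (median 4595). The isotope files hold the secondary ion signal of a major and a minor ion for each spot, per the file headers, and a background row. The deposited signal values are not whole numbers, so the ion counts behind them are unknown and no counting interval is given. The 12 probes of each taxon in the isotope files, 1284 in all, were mostly the brightest of that taxon on the fluorescence arrays (median rank 7). The protein, cellulose, fatty acids and bicarbonate arrays had 1252, 1255, 1218 and 1252 spots with a value, and the others had 1284.

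The headers name the same ion pair in all 14 isotope files, also in those labelled 15N. On the ammonium and nitrate arrays the median ratio of minor to major ion was 0.00367 and 0.00375, close to the natural abundance of 15N, while it was 0.0128 for protein and 0.0118 for amino acids, close to neither natural abundance. The 13C arrays had median ratios of 0.0109 to 0.0111, except nucleic acid with 0.00965, a departure whose cause was not tested. Which ion the second column holds on the protein and amino acid arrays is unresolved. Slopes from those arrays show that the minor ion rose with fluorescence, and their size is not compared with the others, while protein and amino acids are set against each other only relative to each array's own slopes.

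The design assumed enrichment in per mil, and the files hold ion signals. The ratio of the minor to the major ion was therefore turned into delta, in per mil, against a baseline: the median ratio of the 64 probes (5%) with the lowest fluorescence on that array, as the design provided for files that hold ratios. Each fluorescence array was divided by its median over the 1284 probes, and the 3 arrays were averaged. For each taxon and substrate, delta was regressed on scaled fluorescence by least squares through the baseline. The slope is in per mil per unit of scaled fluorescence, where 1 is the array median. A taxon was called labelled where the slope minus 2 standard errors was above 0, and negative where the slope plus 2 standard errors was below 0. At least 5 probes were needed. The standard error covers the spread of probes on 1 array. Every substrate has 1 array and no replicate, so no p-value compares incubations, and the number of arrays limits the precision.

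The steps were tested on simulated data built on the real fluorescence, with noise drawn from the delta of the array's probes below the median fluorescence. On a simulated glucose array, 0.745% of taxa with a true slope of 0 were called, as were 21.8% with a slope of 5, 89.5% with a slope of 20 and 99.5% with a slope of 50. On a simulated ammonium array these shares were 0.426%, 15.3%, 85.3% and 99.8%. On a simulated nucleic acid array they were 1.17%, 4.75%, 5.5% and 16%. The noise was drawn for each probe separately and centred on 0, so it holds no offset shared by the probes of a taxon. These shares therefore do not give the rate of false calls on the real arrays, where 101 of 1496 slopes were called negative.

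Lists of taxa were fixed before the data were examined: plastids, cyanobacteria, archaea, the SAR11, SAR86 and Roseobacter clades, other Alphaproteobacteria, Betaproteobacteria, other Gammaproteobacteria, Deltaproteobacteria, Bacteroidetes and Verrucomicrobia matched at least 1 taxon. The files shorten taxon names, so shortened forms of a fixed term were accepted where they fit 1 list alone. That rule, and a list of 11 eukaryote probe sets, were added after the files were seen. 31 taxa fitted no list, among them names that fit several. A list's median slope was set against 10000 random sets of as many taxa drawn from the same fluorescence tertiles (matched-set permutation test, two-sided), for 6 fixed lists with at least 3 members, with Benjamini-Hochberg adjustment over 83 pairs of list and substrate, and for the eukaryote list over its 14 substrates. The number of substrates per taxon was set against 10000 permutations of the calls within substrates and tertiles. Because these leave out the fluorescence that a taxon shares over substrates, the delta values of whole taxa were also exchanged 10000 times within tertiles before the fit. Profiles were compared with Spearman and Pearson correlations across taxa, which are not independent replicates, with 100000 permutations and adjustment over 91 pairs. Because all slopes share the fluorescence values, delta was also shuffled over probes 100 times.

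The taxa named were chosen by rules set before the data were examined: for each substrate the 3 largest slopes among taxa labelled with each of the 3 fluorescence arrays used alone, the 8 taxa labelled on most substrates (ties by mean fluorescence), the 5 labelled on fewest in the brightest tertile, the brightest taxon of each list, the 5 largest rises and falls of fluorescence from T0, and the largest difference of each related pair. Members of lists with 1 or 2 taxa are named as well, and other taxa outside these rules are said to be so. Alternatives changed the fluorescence array, its scaling, the intercept, the baseline, the slope estimator, the minimum of probes, the threshold and the probes used. Weighting by the error of single spots was not run, since the files hold no error for a spot. An intercept at the median of the 5% of dimmest probes is the baseline already used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.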

Results

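The incubations asked which members of a coastal surface community took up which organic and inorganic substrates within 12 h. Extracted RNA was hybridized to arrays with probe sets for 107 taxa, and 14 isotope arrays gave the enrichment of the bound RNA, 1 for each substrate. A fluorescence label names ammonium and glucose together, so these substrates may have shared a bottle. Whether others did was not resolved. Calls and profiles of different substrates may therefore not come from separate incubations. The 10 substrates with 13C were cellulose, nucleic acid, glucose, cellobiose, fatty acids, lipids, starch, lactose, maltose and bicarbonate, and the 4 with 15N were protein, ammonium, nitrate and amino acids. Fluorescence was measured on 3 arrays, whose median intensity over the probes used was 19840 at T0, 21408 after incubation with nucleic acid and 22297 after incubation with ammonium and glucose. Values for taxa are slopes ± standard error (SE) over probes, in per mil per unit of scaled fluorescence, from 12 probes unless stated. There were no replicate incubations, so errors describe probes on 1 array. They treat the probes of a taxon as independent and do not cover an offset that these probes share. The log major ion signal was alike within taxa to differing degrees. Its intraclass correlation, the share of the spread that lies between taxa, ran from 0.0212 on lipids to 0.846 on nucleic acid. Which minor ion was measured on the protein and amino acid arrays is unresolved, as their ratios lie near neither natural abundance.

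Starch labelled the most taxa, 82 of 107, with a median slope of 18.7 per mil. The nitrogen sources protein, ammonium and nitrate each labelled 71 taxa, with median slopes of 17.6, 11.5 and 15.9 per mil. Among the sugars, glucose labelled 65 taxa (median slope 6.21 per mil), maltose 60 (7.17), lactose 41 (0.768) and cellobiose 25 (0.919). Bicarbonate labelled 67 taxa (median slope 6.96 per mil), nucleic acid 65 (80.5), amino acids 45 (7.64), lipids 30 (4.68), cellulose 20 of 105 (0.454) and fatty acids 5, with a median slope of -0.491 per mil. The nucleic acid array had the lowest median major ion signal, 9016 against 40460 to 324459 on the others. Its baseline ratio was 0.00872, against 0.0108 to 0.0111 on the other 13C arrays, so the size of its slopes may not be comparable with theirs. Delta of single spots followed the major ion signal on the nucleic acid, starch and maltose arrays (Spearman's rho 0.760, 0.598 and 0.500). This limits the results on these arrays, those on maltose included. Slopes were called negative in 101 cases, with 19 negative taxa on lactose, 17 on nucleic acid, 16 on cellulose, 14 on maltose, 10 on bicarbonate, 8 on starch, 6 each on protein and fatty acids, 2 on cellobiose and 1 each on ammonium, amino acids and lipids, so that on cellulose and fatty acids they were about as frequent as labelled taxa.

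**Figure D1:**
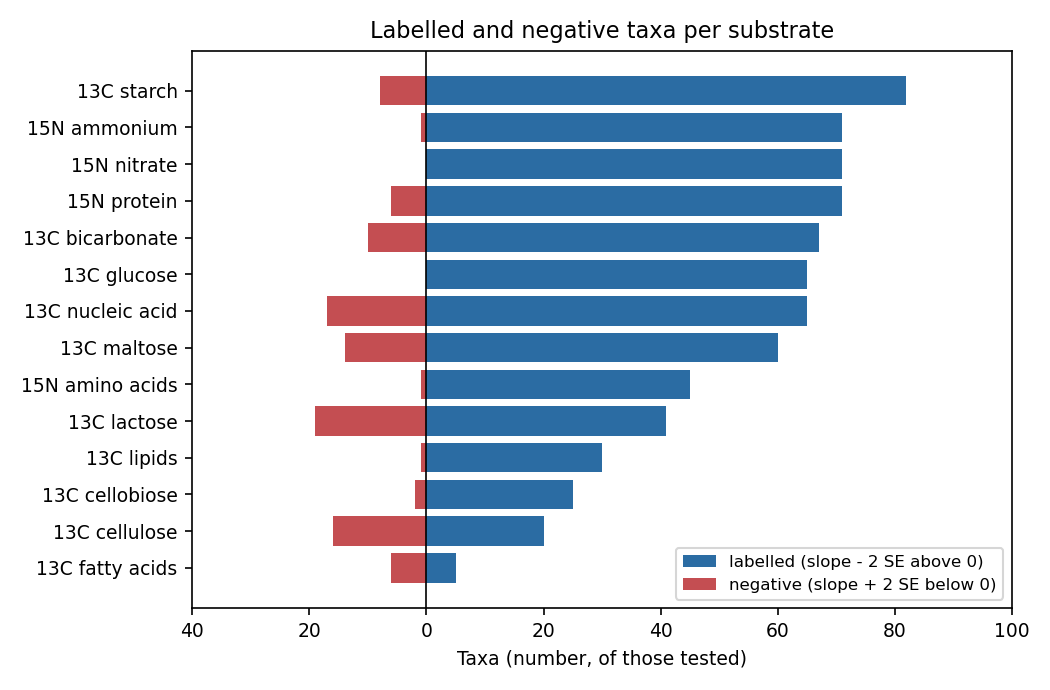
Number of taxa labelled (bars to the right, slope minus 2 standard errors above 0) and negative (bars to the left, slope plus 2 standard errors below 0) on each substrate array. Starch has 82 labelled taxa and fatty acids 5, while negative taxa number 19 on lactose and 0 on nitrate and glucose.

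Taxa that led on a substrate had the largest slopes among those labelled with each of the 3 fluorescence arrays used alone. On protein these were lotka_1 (139 ± 10.8 per mil), roseo_7 (115 ± 11.9 per mil, 11 probes), a member of the Roseobacter clade of marine Alphaproteobacteria, and altero_1 (81.9 ± 5.49 per mil), a gammaproteobacterium. The same 3 taxa led on glucose, with 136 ± 56.0 per mil for altero_1, 80.9 ± 27.3 for roseo_7 and 63.1 ± 20.3 for lotka_1. On amino acids roseo_7 reached 51.2 ± 6.68 per mil, lotka_1 49.96 ± 3.58 and OM60_4, of the other Gammaproteobacteria, 31.7 ± 3.59. Nitrate slopes were led by OM60_5 (96.4 ± 21.3 per mil), OM60_4 (84.9 ± 20.8) and lotka_1 (75.6 ± 23.3). Ammonium slopes were led by the eukaryote probe set dino_3 (97.2 ± 12.8 per mil), crocini_2 (65.4 ± 11.6) and syntropho_1 (53.4 ± 3.03).

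On starch, the Bacteroidetes flavo_1 (79.2 ± 6.97 per mil) and NS4_1 (57.7 ± 4.82) and the eukaryote dino_3 (67.2 ± 7.82) led. Maltose slopes were led by flavo_2 (46.5 ± 8.68 per mil), roseo_7 (38.4 ± 5.01) and roseo_4 (35.7 ± 3.37), and lactose slopes by roseo_5 (23.7 ± 4.55), TM7_1 (19.5 ± 3.41) and sapro_2 (19.1 ± 6.14). On cellobiose flavo_2 (7.83 ± 3.82 per mil), dino_3 (7.50 ± 2.62) and roseo_1 (7.46 ± 2.32) led. Cellulose slopes were led by OSC116_2 (35.0 ± 5.49 per mil), OSC116_1 (30.1 ± 6.03) and roseo_11 (19.99 ± 3.42). Lipid slopes were led by OM182_1 (36.9 ± 9.87 per mil), OM60_4 (23.4 ± 3.64) and roseo_7 (23.3 ± 8.95), and fatty acid slopes by acidi_1 (9.46 ± 3.96, 10 probes), OM60_4 (6.20 ± 2.49) and TA18_1 (5.37 ± 1.30, 10 probes). Bicarbonate slopes were led by OSC116_1 (23.0 ± 1.72 per mil), OM60_4 (20.7 ± 2.30) and the eukaryote dino_2 (19.8 ± 2.80), and nucleic acid slopes by nitroso_1 (356 ± 28.1), gamma_1 (285 ± 24.9) and flavo_2 (248 ± 37.4).

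Calls varied with the fit and the baseline. With a free intercept, which asks whether the brighter probes of a taxon are also the more enriched, 311 calls were made over all substrates, against 718, while median slopes stayed near those through the baseline on protein (18.0 per mil), nitrate (15.8), glucose (6.69) and bicarbonate (8.05) and moved on nucleic acid (80.5 to 48.2), lipids (4.68 to 0.558), maltose (7.17 to 10.3), lactose (0.768 to 4.50), cellulose (0.454 to 1.32), cellobiose (0.919 to 1.75) and fatty acids (-0.491 to 3.16). Of the named slopes, 7 turned negative: altero_1 and roseo_7 on glucose (-191 and -63.0 per mil), nitroso_1 on nucleic acid (-280), OM182_1 on lipids (-11.8), roseo_5 on lactose (-39.4), dino_3 on cellobiose (-3.27) and acidi_1 on fatty acids (-2.39). In a permutation of delta over the probes of a taxon, 339 cases had an unadjusted permutation p under 0.05, against 74.8 by chance, and 130 passed after adjustment. With the background row of each array as 0 per mil, labelled taxa numbered 21 on bicarbonate, 28 on nucleic acid and 1 on lipids, against 44 on cellulose, 41 on cellobiose, 63 on lactose and 32 on fatty acids, and negative taxa numbered 45 on bicarbonate, 50 on nucleic acid and 69 on lipids. Starch did not lead in every alternative: that row as 0 gave 100 taxa for nitrate, 80 for glucose and 63 for starch, a free intercept 41 for nitrate and 36 for starch, the brighter probes 51 and 50, and the permutation over probes 42 for protein, 40 for nitrate and 39 for starch before adjustment, and 27 for maltose, 23 for nitrate and 22 for starch after it. The median slope on nucleic acid was 41.8, 54.5 and 55.7 per mil with the T0, the nucleic acid and the ammonium and glucose fluorescence array alone, and -26.7 with the background row.

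Among the fixed lists, Bacteroidetes, a phylum whose marine members are known for degrading polysaccharides, stood apart on starch. All 17 taxa matched to the list were labelled there, 12 of them matched by shortened names under a rule added after the files were seen, with a median slope of 39.1 per mil, against 15.8 for the remaining taxa, and flavo_2, their brightest member, was labelled on 12 substrates. The remaining taxa include 31 that fitted no list by name, some of which may also be Bacteroidetes, and random sets draw on them too. The contrast is therefore one of the matched list and not of the whole phylum. The median of random sets of equal brightness was 18.7 per mil, and the difference of 20.5 passed the matched-set permutation test (two-sided p = 0.0004, adjusted p = 0.0332). With medians this was the only 1 of 83 pairs of list and substrate past an adjusted 0.05. With means it passed as well (difference 19.7 per mil, adjusted permutation p = 0.0083), as did the SAR86 clade on cellulose (-18.6, permutation p = 0.0002, the smallest possible, adjusted p = 0.0083, range over alternatives 0.0083 to 1). With only the 5 Bacteroidetes whose name holds a full fixed term the difference was 20.6 per mil and did not pass (permutation p = 0.0418, adjusted p = 0.213). Bacteroidetes were also labelled in 15 of 17 cases on protein, 15 on nitrate, 14 on glucose, 12 on maltose and 11 on ammonium, but in 0 on fatty acids and 1 on cellulose. The delta of single spots followed the major ion signal on the starch array (Spearman's rho 0.598 over spots), and with delta adjusted for that signal the Bacteroidetes difference on starch was 16.2 per mil (adjusted permutation p = 0.0166, range over alternatives 0.0083 to 0.879). The starch result was not past the threshold without saturated probes (difference 13.5 per mil, adjusted permutation p = 0.135), with a free intercept (10.5, p = 0.879) or with only the brighter probes (9.81, p = 0.567), over a range of adjusted p from 0.0083 to 0.879 in all alternatives.

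**Figure D2:**
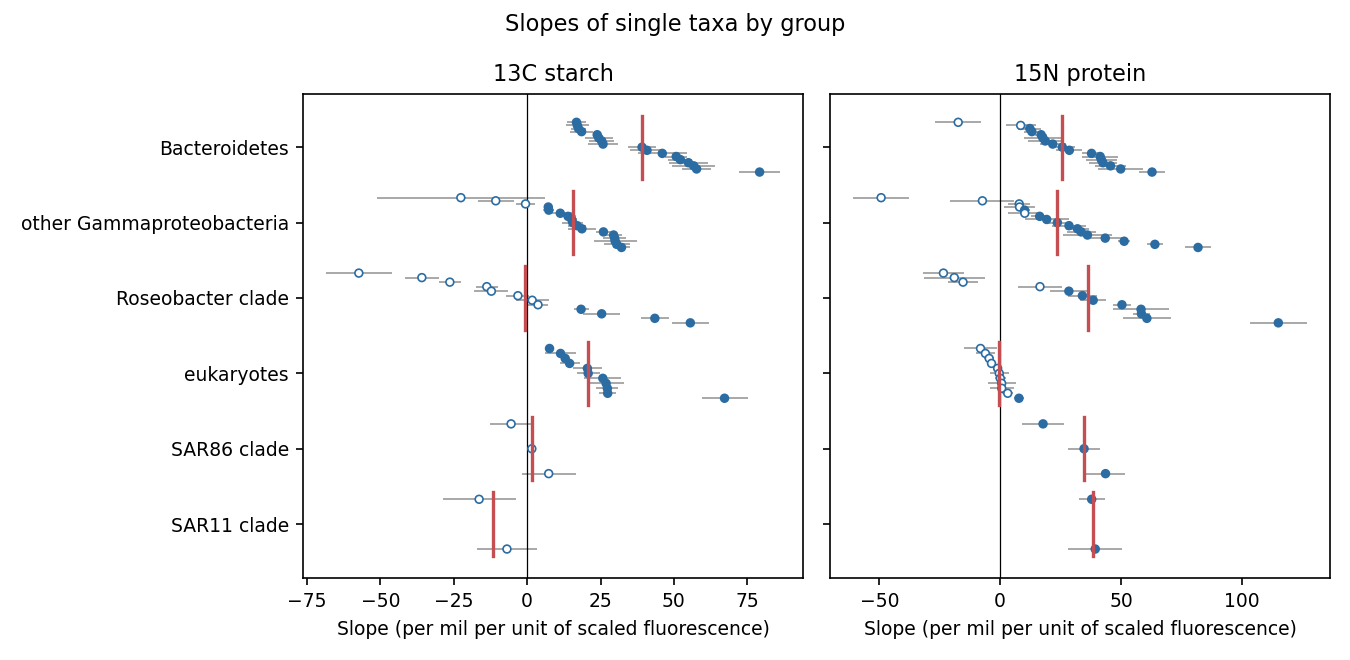
Slope of each taxon on the 13C starch and 15N protein arrays, by group (filled points labelled, open points not labelled, grey bars standard error over probes, red lines group medians; horizontal axes in per mil per unit of scaled fluorescence). All 17 Bacteroidetes are labelled on starch with a median of 39.1 per mil, and 1 of 11 eukaryotes is labelled on protein.

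The 11 eukaryote probe sets were low on protein. Only ciliate_2 was labelled on protein (7.78 ± 2.08 per mil), a value singled out after it was seen. The eukaryote median of -0.362 per mil compared with 17.8 in random sets of equal brightness (difference -18.1, permutation p = 0.0014, adjusted p = 0.0196). On ammonium, 10 of the 11 were labelled and the median slope exceeded that of random sets by 7.68 per mil (percentile 97.7), which did not pass after adjustment (permutation p = 0.0454, adjusted p = 0.127). All 11 were labelled on starch (median 20.8 per mil), 9 on nucleic acid, 7 on bicarbonate (7.93), 5 on glucose (2.18) and 2 on maltose. The differences from random sets on glucose (-4.94 per mil), maltose (-9.09) and lactose (-4.14) did not pass (permutation p = 0.0106, 0.0202 and 0.0204, adjusted p = 0.0714 for each), nor did that on nitrate (-8.74 per mil, percentile 3.8, permutation p = 0.0856, adjusted p = 0.2). With means in place of medians the eukaryotes lay below random sets past an adjusted 0.05 on 5 substrates: protein (-24.4 per mil, adjusted permutation p = 0.00187, range over alternatives 0.00187 to 0.0336), glucose (-9.78, 0.00187, 0.00187 to 0.582), maltose (-11.0, 0.00187, 0.00187 to 0.715), nitrate (-14.2, 0.0098, 0.0098 to 1) and lactose (-5.19, 0.0140, 0.0140 to 0.715). The raw permutation p of these means was 0.0002 for protein, the smallest possible, 0.0004 for glucose and maltose, 0.0028 for nitrate and 0.005 for lactose. The list was drawn up after the files were seen, and the ion measured on the protein array is unresolved.

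Roseobacter clade taxa were labelled on glucose and maltose in 9 of 12 cases each, on protein in 8 (median 36.3 per mil) and on amino acids in 7 (14.0), but on starch in 4, with 5 negative and a median of -0.708 per mil. Their medians on amino acids and starch lay at percentiles 99.6 and 0.32 of the random sets, which did not pass after adjustment over the 83 pairs (permutation p = 0.0084 and 0.0066, adjusted p = 0.129 for both). The same holds for protein (percentile 99.4, permutation p = 0.0112, adjusted p = 0.129) and glucose (99.3, permutation p = 0.0144, adjusted p = 0.133). Over 16 settings the clade passed an adjusted permutation p of 0.05 in 1 on starch (lowest 0.0498), 1 on maltose (0.0498) and 2 on lipids (0.0166). It passed in 0 on amino acids, protein and glucose. Their brightest member, roseo_12, was labelled on 7 substrates. The 17 other Gammaproteobacteria were labelled on starch in 14 cases and on protein, ammonium, nucleic acid and maltose in 12 each. Their median of 3.42 per mil on fatty acids was the highest of the 6 tested lists (percentile 99.8, permutation p = 0.0048, adjusted p = 0.129), although only 2 of the 17 were labelled on fatty acids. That difference passed an adjusted permutation p of 0.05 in 2 of 16 settings (lowest 0.0166).

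Smaller lists are given as counts. The 2 taxa of the SAR11 clade, small-celled Alphaproteobacteria of surface waters, were both labelled on protein (median 38.6 per mil), glucose (14.7), cellulose (14.5) and bicarbonate (9.58), and neither on ammonium, starch or amino acids, and SAR11_2 was labelled on 5 substrates. All 3 SAR86 taxa were labelled on protein (median 34.7 per mil) and negative on cellulose (-16.4), and SAR86_2 was labelled on 6 substrates. Both Betaproteobacteria, OM43_1 and OM43_2, were labelled on nitrate (median 54.6 per mil) and protein (20.4), and neither on any of the 5 sugars and polysaccharides other than glucose, which labelled 1 of them. The 3 Deltaproteobacteria were all labelled on ammonium (median 10.3 per mil), starch (22.2) and nucleic acid (149), and delta_1 on 10 substrates. The 3 Verrucomicrobia were all labelled on starch (28.2 per mil) and glucose (11.4), and verru_2 on 9 substrates. The 2 other Alphaproteobacteria, SAR116_1 and rickett_1, were both labelled on nitrate, starch, lactose, maltose, bicarbonate and nucleic acid, and SAR116_1 on 9 substrates. The archaeal set euryarch_1 was labelled on cellulose alone.

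Cyanobacteria and plastids fix bicarbonate in the light, so their bicarbonate slopes bear on the labels and the method. Of these 3 sets, dino-plast_1 was labelled on bicarbonate (16.7 ± 4.08 per mil), while strameno_1 (0.0958 ± 2.05) and cyano_1 (-1.94 ± 3.48) were not. Their median of 0.0958 per mil lay below the 5.32 of random sets (percentile 16.6), and a matched-set permutation test for a higher value gave one-sided p = 0.834. dino-plast_1 was labelled on 6 substrates and cyano_1 on 7, the latter with 28.6 ± 4.06 per mil on ammonium. The light conditions are not given in the sources used here.

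Taxa differed in the breadth of substrates they were labelled on. OM60_4 was labelled on all 14 substrates, OM60_5 and rhizo_1 on 13, flavo_2, OM60_3, TA18_1 and syntropho_1 on 12 and OM60_1, the brightest of 6 taxa tied at that count, on 11. OM60_2 was labelled on 7, a set named after its value was seen. In the brightest tertile the narrowest were dino_4 and sapro_1 with 3 substrates, OM43_1 with 4, and ciliate_2 and dino_1 with 5. The median over 107 taxa was 6 substrates, 21 taxa were labelled on 10 or more and 14 taxa on 3 or fewer. The variance of the counts was 8.59 against 5.28 when calls were permuted within substrates and brightness tertiles, a ratio of 1.62 (one-sided permutation p = 1e-04, the smallest that the permutations can give). It was 5.24 when the delta values of whole taxa were exchanged within tertiles before the fit, so that each taxon kept its fluorescence (ratio 1.64, permutation p = 1e-04, again the smallest possible). Brightness still counted, since the median number of substrates was 4.5 in the dimmest tertile, 7 in the middle and 8 in the brightest. It also varied within tertiles, with mean fluorescence from 0.475 to 0.977 in the dimmest and 1.47 to 2.84 in the brightest. Neither comparison separates a taxon's delta from its brightness within a tertile. Whether taxa differed in breadth beyond brightness is therefore not settled.

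Related substrates were compared within taxa, with each array's slopes divided by their median because the amounts added are not given in the sources used here. Between glucose and maltose, 32 taxa had the higher relative slope on glucose, most of all altero_1 (slopes 136 ± 56.0 and 18.6 ± 6.66 per mil), and 13 on maltose, most of all nitroso_1 (5.63 ± 4.07 and 32.5 ± 3.49). Between maltose and starch, the polymer from which it is released, 29 taxa were relatively higher on maltose, led by roseo_7 (38.4 ± 5.01 on maltose and 25.4 ± 6.36 on starch), and 32 on starch, led by dino_3 (-22.6 ± 3.26 on maltose and 67.2 ± 7.82 on starch). Ammonium exceeded nitrate in 21 taxa, led by dino_3 (97.2 ± 12.8 against 19.3 ± 4.95 per mil), and nitrate exceeded ammonium in 16, led by verru_1 (61.6 ± 15.4 against -6.11 ± 3.27). Amino acids exceeded protein in 14 taxa, led by BD1-5_1 (28.6 ± 2.22 against 10.01 ± 3.98 per mil), and protein exceeded amino acids in 14, led by polari_1 (41.9 ± 6.29 against -12.9 ± 7.21), relative to each array's median only, since the ion on both arrays is unresolved and their slopes may not be comparable in size. Each of these differences is over 2 standard errors of the difference. The counts depend on the scaling: in the same order they were 32 and 14, 21 and 38, 21 and 16, and 16 and 9 with slopes divided by their 75th percentile, and 29 and 17, 10 and 61, and 8 and 25 for the first 3 pairs without scaling. For the remaining pairs the median slope of an array was under 2 per mil, a limit set after seeing the data, and slopes are compared without scaling: starch exceeded cellulose in 79 taxa and was lower in 10, glucose exceeded cellobiose in 56 and was lower in 0, glucose exceeded lactose in 56 and was lower in 3, and maltose exceeded lactose in 47 and was lower in 7. Maltose exceeded cellobiose, its isomer with the other glucose linkage, in 49 taxa and was lower in 12. Cellobiose exceeded lactose in 22 taxa and was lower in 27, cellobiose exceeded cellulose in 24 and was lower in 14, and lipids exceeded fatty acids in 16 and were lower in 0. These unscaled counts also move with the amount and label of each substrate. Divided by the 75th percentile, starch was higher than cellulose in 36 taxa and lower in 11, glucose than cellobiose in 17 and 7, glucose than lactose in 38 and 11, and maltose than lactose in 29 and 8. Maltose was then higher than cellobiose in 15 and lower in 15, cellobiose than lactose in 18 and 13, cellobiose than cellulose in 21 and 12, and lipids than fatty acids in 7 and 1. With a free intercept the scaled pairs gave 13, 15, 14 and 11 differing taxa for glucose and maltose, maltose and starch, ammonium and nitrate, and amino acids and protein.

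Substrate profiles across taxa were alike for several pairs. The strongest relation joined protein and glucose (Spearman's rho 0.651, Pearson's r 0.667 over 105 taxa), where altero_1, roseo_7 and lotka_1 were high on both, followed by nitrate and glucose (rho 0.636, r 0.567), ammonium and starch (rho 0.559, r 0.573) and lactose and maltose (rho 0.533, r 0.519). Of 91 pairs, 21 passed an adjusted permutation p of 0.05 by Spearman's rho and 24 by Pearson's r, and all 21 were positive. Each of the 4 had a permutation p of 1e-05, the smallest that the permutations can give, and an adjusted permutation p of 0.000114. These p-values test against a correlation of 0, but slopes share their fluorescence values. Shuffling delta over probes gave a median rho of 0.130 over pairs. The shuffle keeps each array's delta values but removes their relation to fluorescence, so its rho does not come from shared fluorescence alone. Of the 21 pairs, 8 exceeded the highest of their 100 shuffles, and over all 91 pairs 9 lay above every shuffle and 11 below every shuffle. With delta shuffled over probes the highest of 100 rho values was 0.501 for protein and glucose, 0.465 for nitrate and glucose and 0.307 for lactose and maltose, but 0.641 for ammonium and starch, above the measured value. Fatty acids and lipids had a rho of 0.407 (r 0.326, permutation p = 5e-05 and 0.00124, adjusted p = 0.000379 and 0.00664) with 0.220 as the highest shuffle, and ammonium and nitrate a rho of 0.333 with 0.555.

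**Figure D3:**
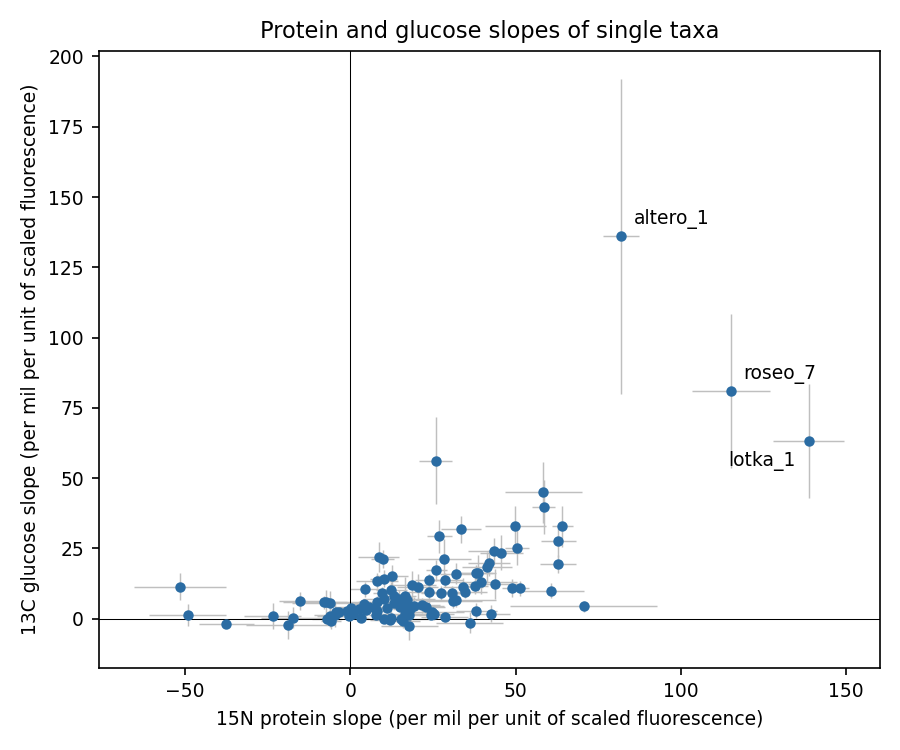
Slopes of single taxa on the 15N protein array (horizontal) and the 13C glucose array (vertical), in per mil per unit of scaled fluorescence, with standard errors over probes. altero_1, roseo_7 and lotka_1 are marked, with glucose slopes of 136, 80.9 and 63.1 per mil.

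Fluorescence of the incubated arrays was set against T0 to see how the rRNA bound for each taxon differed. The 5 taxa furthest below T0, with 1 direction on both incubated arrays, were oceano_6 (log2 ratio -0.72 with nucleic acid and -0.62 with ammonium and glucose), OM60_3 (-0.46 and -0.48), fluvii_3 (-0.37 and -0.48), dino_4 (-0.17 and -0.64) and OM60_1 (-0.39 and -0.41). The 5 furthest above T0 were roseo_4 (0.18 and 0.39), roseo_7 (0.23 and 0.30), dino_3 (0.25 and 0.28), SAR92_1 (0.16 and 0.35) and OM27_1 (0.24 and 0.17). These 10 directions were the same without scaling and after quantile normalization. The incubated arrays differed from each other by an SD of 0.15 over taxa, and 5 of 107 taxa lay beyond 2 SD of that in both, 0 higher and 5 lower. These 5 were oceano_6, OM60_3, fluvii_3, OM60_1 and OM60_5 (-0.36 and -0.39), the last named after its values were seen, while dino_4 lay within 2 SD with nucleic acid. Without scaling the split was 4 higher and 2 lower, and after quantile normalization 1 and 3. The medians of the incubated arrays lay 0.11 and 0.17 above T0 on the log2 scale. Of the 17 other Gammaproteobacteria, 11 were lower than T0 on both arrays after median scaling (median -0.20), but 6 were lower and 5 higher without scaling, and 9 lower and 3 higher after quantile normalization. With 1 array per condition no test was made.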

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

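The predictions of these tests, those of incorporated label and of list membership included, were all written or put in final form only after the results were seen. The background row of the bicarbonate array, which holds no probe of a taxon, lay 12.8 per mil above the baseline, beyond the spread of the low-fluorescence probes (SD estimated from the median absolute deviation, 6.49 per mil).

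Nucleic acid and starch labelled 65 and 82 taxa, and delta on both arrays followed the major ion signal of the spot (Spearman's rho 0.760 and 0.598). After a trend on that signal was removed, delta was set to 0 again at the low-fluorescence probes, so the calls still rest on that baseline. On starch 94 taxa were then labelled and 1 negative, which argues against such a trend as the whole cause. On nucleic acid 70 were labelled and 2 negative, which cannot decide, since the baseline of that array stays open. A baseline that lies under the array background is argued against only as the whole cause for starch. There, 63 taxa were labelled and 19 negative with the background row as 0 per mil. The low-fluorescence baseline had given 82 and 8, and the median slope fell from 18.7 to 8.92 per mil, so the starch calls depend on the baseline in part. Such a baseline stays open for nucleic acid, where 28 were labelled and 50 negative. Incorporated label predicts that delta rises with fluorescence within taxa, which held by sign in 73.8% of all taxa on nucleic acid and 81.3% on starch, above the highest shares when delta was permuted within taxa (64.5% and 62.6%). Incorporated label is not excluded on either array, but other effects that rise with fluorescence were not tested, so for starch as for nucleic acid the cause stays open. On maltose delta also followed the major ion signal (rho 0.500). With that trend removed, 69 taxa were labelled and 12 negative, against 60 and 14 before. The cause was not tested further there.

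Glucose, protein and nitrate slopes were correlated across taxa. Shared fluorescence values are argued against for glucose with protein and with nitrate. The lower of these had a rho of 0.636 against 0.465 for the highest shuffle. Protein with nitrate, at 0.476 against 0.558, lay within the shuffles. The shuffles also remove the relation of delta to fluorescence, so they cannot decide whether shared fluorescence accounts for that pair. After the major ion signal was adjusted for, the glucose pair nearer its highest shuffle had 0.610 against 0.523, which argues against that signal for the glucose pairs, while protein with nitrate, at 0.445 against 0.552, leaves it open. After each list's median was taken off 1 of the glucose pairs lay just under its highest shuffle (0.544 for both) and protein with nitrate below it (0.431 against 0.533), so list membership stays open. That the same taxa were active on glucose, protein and nitrate is a hypothesis found and tested on the same arrays.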

How the results depend on the processing

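The settings with the background row, background-subtracted fluorescence, the major ion signal, saturated probes, fewer arrays, slopes without scaling, all fluorescence probes, full names and exchanged delta were chosen only after the data were seen, and the cause of a change was not tested unless stated. Labelled taxa over all substrates numbered 718. With a free intercept there were 311 (protein 37, cellulose 7, nucleic acid 17, ammonium 26, nitrate 41, glucose 23, cellobiose 9, amino acids 21, lipids 3, starch 36, lactose 15, maltose 37, bicarbonate 35), with median slopes about as large on protein (18.0 against 17.6 per mil) and starch (15.7 against 18.7) but smaller on nucleic acid (48.2 against 80.5) and lipids (0.558 against 4.68), and related pairs differed in 13 (glucose and maltose), 15 (maltose and starch), 11 (amino acids and protein) and 14 taxa (ammonium and nitrate). Of the 42 named slopes, those of nitroso_1 on nucleic acid (-280), altero_1 (-191) and roseo_7 on glucose (-63.0), dino_3 on cellobiose (-3.27), acidi_1 on fatty acids (-2.39), OM182_1 on lipids (-11.8) and roseo_5 on lactose (-39.4) turned negative with it. The permutation over probes with Benjamini-Hochberg adjustment gave 130 (protein 20, nucleic acid 5, ammonium 6, nitrate 23, glucose 8, starch 22, lactose 2, maltose 27, bicarbonate 17, and 0 on cellulose, cellobiose, amino acids, fatty acids and lipids, where unadjusted permutation p-values under 0.05 numbered 11, 10, 23, 4 and 4). Using only probes above the median fluorescence removes dim taxa and gave 476 (protein 45, nucleic acid 43, ammonium 45, glucose 41, cellobiose 13, starch 50, lactose 25), with 24, 34 and 16 differing taxa for glucose and maltose, maltose and starch, and amino acids and protein. At 3 standard errors the counts were 12 for cellulose, 43 for glucose, 4 for cellobiose, 1 for fatty acids and 15 for lipids. The background row as baseline gave 44 for cellulose, 28 for nucleic acid, 41 for cellobiose, 32 for fatty acids, 1 for lipids, 63 for lactose and 21 for bicarbonate, and turned roseo_7 on lipids to -0.688 per mil. It moved the median slope to -3.17 per mil on bicarbonate, -13.6 on lipids, 8.92 on starch, 5.63 on ammonium and 24.8 on nitrate. Cellobiose had 15 with the ammonium and glucose fluorescence alone, 16 with the median ratio and 13 when each probe was left out in turn, and fatty acids had 9 with T0 fluorescence alone, 14 after quantile normalization, 3 when each probe was left out, 17 after adjustment for the major ion signal and 3 without saturated probes. The nucleic acid, starch, maltose, lactose and cellulose arrays were left out as doubtful in 1 setting. There were then 450 calls and 10 correlated profile pairs, with fewer arrays tested. List pairs past the threshold numbered 0, since the pair that passed, Bacteroidetes on starch, lay on an array left out. Profile pairs numbered 13 with the median ratio. List pairs past the threshold numbered 2 with nucleic acid fluorescence alone, 2 with means in place of medians, 5 with background-subtracted fluorescence, 0 with the brighter probes or without saturated probes, and 0 with only members whose name holds a full fixed term. Eukaryotes passed on 1 substrate, but on 4 with nucleic acid fluorescence alone, 4 with the median ratio, 4 with the background row, 2 with the brighter probes, 2 with background-subtracted fluorescence, 2 after adjustment for the major ion signal and 5 with means. Bacteroidetes on starch differed by 10.5 per mil with a free intercept, 9.81 with the brighter probes 13.5 without saturated probes and 20.6 with full names alone (adjusted permutation p = 0.213, range over alternatives 0.0083 to 0.879). Amino acids and protein differed in 55 taxa without scaling, a count that assumes the same ion on both arrays. Fluorescence beyond T0 was found in 3 taxa with the brighter probes and in 3 with all fluorescence probes. A minimum of 3 probes gave identical values and a minimum of 10 changed no count of labelled taxa, so neither tests stability. Weighting by measurement error was not run because the files hold none, and the intercept at the 5% of dimmest probes is the baseline already used. The 3 standard errors and the leaving out of each probe change calls alone, so they give no value for profiles, lists or pairs, and the phototrophs could not be tested with only the brighter probes. The spread of substrates per taxon (ratio 1.37 to 2.97, permutation p = 1e-04, the smallest possible, in each), the low eukaryote slopes on protein (difference from random sets -15.9 to -24.8, by median or mean) and the phototrophs on bicarbonate (difference -2.25 to -6.42) kept direction and side of the threshold in every alternative run. Of 570 values for the named slopes under 14 alternatives, 528 stayed labelled, 34 were no longer labelled and 8 turned negative, and a free intercept kept 18 of the 42. The named slopes were chosen as labelled with each of the 3 fluorescence arrays alone. Those 3 alternatives, and fluorescence matched to the incubation, therefore kept all 42 by rule and do not test stability. No paired analysis was possible because every group holds 1 array. At low signal over background, delta of the low-fluorescence probes varied by an SD, estimated from the median absolute deviation, of 164 per mil on the nucleic acid array and of 6.25 to 30.4 on the others.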

Other observations

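The tests on eukaryotes in this part were chosen, and its taxa singled out, only after the results were seen. The eukaryote sets differed among themselves: dino_3 combined an ammonium slope of 97.2 ± 12.8 per mil with -22.6 ± 3.26 on maltose, and dino_4, the brightest of the list, was labelled on 3 substrates, with 7.63 ± 1.27 per mil on starch and 3.13 ± 1.89 on ammonium. The sets amoebophr_1 (8.71 ± 1.97 per mil), radiola_1 and oikopleura_1 (23.7 ± 4.89) were labelled on ammonium, and ceratium_1 reached 18.2 ± 2.94 per mil on bicarbonate. Starch labelled the phototroph sets strameno_1 (37.3 ± 3.47 per mil), cyano_1 (45.4 ± 5.73) and dino-plast_1 (14.1 ± 2.69). The single shewa_1 set, the dimmest of all taxa, was labelled on 0 substrates.

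The eukaryote sets lay above the middle of matched random sets on ammonium (percentile 97.7) and bicarbonate (62.7), and below it on glucose (0.24) and protein (0.02). A preference for inorganic substrates is argued against by nitrate, where they lay at percentile 3.8, below random sets by their means (-14.2 per mil, adjusted permutation p = 0.0098, range over alternatives 0.0098 to 1), although not past the threshold by their medians. The major ion signal of their spots is argued against for the low protein value, since 5, 2 and 4 of the 11 lay in the low, middle and high tertile of that signal, and their median lay below random sets from the same tertiles (difference -17.3 per mil, two-sided permutation p = 0.0032, a single test without adjustment). Which ion the protein array measured is unresolved, and a fraction under 1 micron would leave out whole cells of such eukaryotes, so whether the RNA came from them stays open.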
